A study of Drosophila melanogaster with 2 samples.

How the data were processed

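RNA was prepared with Trizol from about 20 thoraces of 3-day-old male flies per genotype and treated with DNase, and libraries were built with a NEBNext Ultra II kit, per the labels' protocols. The muscle-driven RNA interference targeted pink1 in 1 library and GFP in the control library. CASAVA 1.9, STAR 2.6.1a and featureCounts 1.6.3 are named, without role or order, per the submitters' processing notes. The genome build, annotation, strand setting and read layout are not given in the sources used here.

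The deposited table held 1 value per gene and library for 17490 FlyBase identifiers, without naming its unit. The values were taken as RPKM computed by the authors, because they behaved as reads scaled by exon length and by the total of assigned reads: multiplied by merged exon length from the Ensembl 115 annotation, 97.7% of values above 0 in each library were whole multiples of a common step, within 0.02 reads (14630 genes in the pink1 RNAi library and 13972 in the control). They would be called FPKM had read pairs been counted. The size of that step gave the assigned reads per library, 25463258 and 24463867, and the reads behind each gene's value. The RPKM columns summed to 505655 and 609671. Symbols, positions and exon lengths came from the same annotation, where 17216 identifiers matched and 274 did not. Members of the fixed gene groups without a match, such as InR, Tor and S6k, were not analysed here.

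Genes with a mean of at least 1 RPKM over both libraries were measured genes, 9507 in all. The size of a difference was log2((pink1 + 0.5)/(control + 0.5)), with the pseudocount of 0.5 in RPKM, and a gene counted as higher or lower at an absolute log2 ratio of at least 1. Fold values in the text are plain ratios of RPKM. Intervals of ratios are exact 95% binomial intervals on the recovered reads, and those of read shares are Wilson intervals. With 1 library per genotype no p-value was computed. The planned design allowed for counts, and since the table held RPKM, its branch for other units was used, with values as deposited and no interval in the size rule.

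For 25 gene groups and 8 sets of tissue markers, all fixed before the data were examined along with the size rule and the named genes, the median log2 ratio of measured members was computed where at least 5 were measured. Each median was also given relative to the median of all measured genes, with an order-statistic 95% interval over members. Its percentile was taken among 10000 random lists of the same size, drawn from 20 bins of mean expression, and describes these 2 libraries only. Medians between the 2.5 and 97.5 percentiles were called inside the range. A further 5 groups were added after the data were seen.

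The genes named were Pink1, park and Mef2, the 12 highest and the 12 lowest past the size rule with a mean of at least 10 RPKM, and within each group up to 4 measured members with the largest absolute log2 ratio plus the 2 most abundant. Not every gene the rule allows is described. Genes outside it are said to be named after their values were seen.

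Exon overlap was computed for each gene, since reads from overlapping genes may be counted for both. Of 132 genes lying wholly inside the exons of a gene on the opposite strand 121 had values above 0, and of 415 such genes on the same strand 356 did. Of all genes 6.87% had at least 50% of their exons covered by another gene, and named genes of that kind are given as uncertain.

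Alternatives tried were the median ratio set to 1, totals without the 20 most abundant genes, pseudocounts of 0.1 and 2, the deeper library thinned to the depth of the other, no filter on low values and a minimum of 10 RPKM. Chosen after seeing the data were totals without the mitochondrially encoded genes, the size rule on recovered reads with a counting interval, protein-coding genes only, and the cytochrome P450 and cuticle lists without Cyp40 and Cpr, genes of another kind that share the symbol prefix.

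The procedure was tested on simulated counts for 16855 genes with Poisson counting noise only and 200 genes changed in the same 2-library comparison. Of the genes made 3-fold higher 100% were called, of those made 3-fold lower 97.5%, and of those changed 4-fold or 8-fold 100%. Of 8856 unchanged measured genes 18 (0.203%) passed the size rule. Counting intervals covered the simulated ratio for 95.9% of 10605 genes. A simulated group of 30 genes raised 1.5-fold reached percentile 100, and an unchanged group percentile 14.9. Unchanged genes had the same rate in both simulated libraries, so the lower mitochondrial read share of the pink1 RNAi library was not simulated. Spread between animals was not simulated either. These shares therefore cover counting noise alone and are no rate of false calls on the deposited scale.

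Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.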

Results

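The data were muscle transcript profiles of 3-day-old male fruit flies (Drosophila melanogaster) from 2 RNA sequencing libraries, each made from about 20 dissected thoraces. In 1 library RNA interference against pink1 was switched on by the dMef2 driver, which is active in muscle. The other library, the control, carried an RNA interference construct against GFP, a jellyfish protein that flies do not make. Each genotype was represented by 1 library, so no difference given here has a replicate check. Any other difference between the genotypes goes with the knockdown and cannot be separated from it. The deposited values were RPKM, reads scaled by exon length and by the total of assigned reads, for 17490 gene identifiers. They implied 25463258 assigned reads in the pink1 RNAi library and 24463867 in the control, and 14866 and 14205 genes had values above 0. Intervals around ratios of reads cover counting error only. The comparison addressed which muscle transcripts differ when pink1 is silenced, within a study of the part PINK1 plays in growth inhibition linked to PTEN mutations.

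Pink1, the targeted gene, encodes a mitochondrial kinase that marks damaged mitochondria for removal. It lay at 12.7 RPKM in the pink1 RNAi library and 110.0 RPKM in the control (1049 and 8715 reads), which was 8.65-fold lower, with a 95% interval of 8.11 to 9.23. Its log2 ratio was -3.06, and it was among the 12 lowest of the abundant genes. Pink1 (FBgn0029891) spans 6683798 to 6687302 on the plus strand of chromosome X in the BDGP6 annotation of Ensembl, to which genes were matched by FlyBase identifier. The build used by the authors is not given in the sources used here. CG44303, whose exons lie to 85.4% within those of Pink1, was also lower, at 4.24 against 23.2 RPKM, but its reads cannot be separated from those of Pink1. The ubiquitin ligase gene park, the partner of Pink1 in mitochondrial quality control, lay at 4.68 against 3.85 RPKM, and its ratio of 1.21 had an interval of 0.982 to 1.5 that included 1. Exons of park overlap an antisense gene by 63.8%, so its values are uncertain. Mef2, the muscle transcription factor whose driver was used, lay at 19.6 and 15.6 RPKM, a log2 ratio of 0.32 on the deposited scale that turned to -0.21 relative to the median of all genes.

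Transcripts of the mitochondrial genome took up a much smaller part of the pink1 RNAi library. They made up 13.2% of its assigned reads (95% Wilson interval 13.1 to 13.2) and 36.8% of those of the control (36.8 to 36.8). The large mitochondrial ribosomal RNA mt:lrRNA alone held 7.97% and 21.6% of reads, and the 20 most abundant genes together held 26.1% and 45.4%. Because RPKM divides by all assigned reads, a lower mitochondrial share raises the values of other genes in the pink1 RNAi library. Among 9507 genes with a mean of at least 1 RPKM, 8511 (89.5%) had a log2 ratio above 0, and the median ratio of all genes was 0.53, or 1.44-fold. Group medians are therefore given below relative to that median, unless the deposited scale is named.

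On the deposited scale 1618 genes were at least 2-fold higher in the pink1 RNAi library and 82 were at least 2-fold lower, so that 95.2% of these genes were higher. With the median ratio set to 1, the counts were 491 higher and 285 lower, and 63.3% were higher. Leaving the 20 most abundant genes out of the total gave 768 and 251 (75.4% higher), and leaving out the mitochondrially encoded genes gave 714 and 243 (74.6% higher). Each fold change behind these counts is on the log2(RPKM + 0.5) scale, which understates changes of genes with low values.

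**Figure D1:**
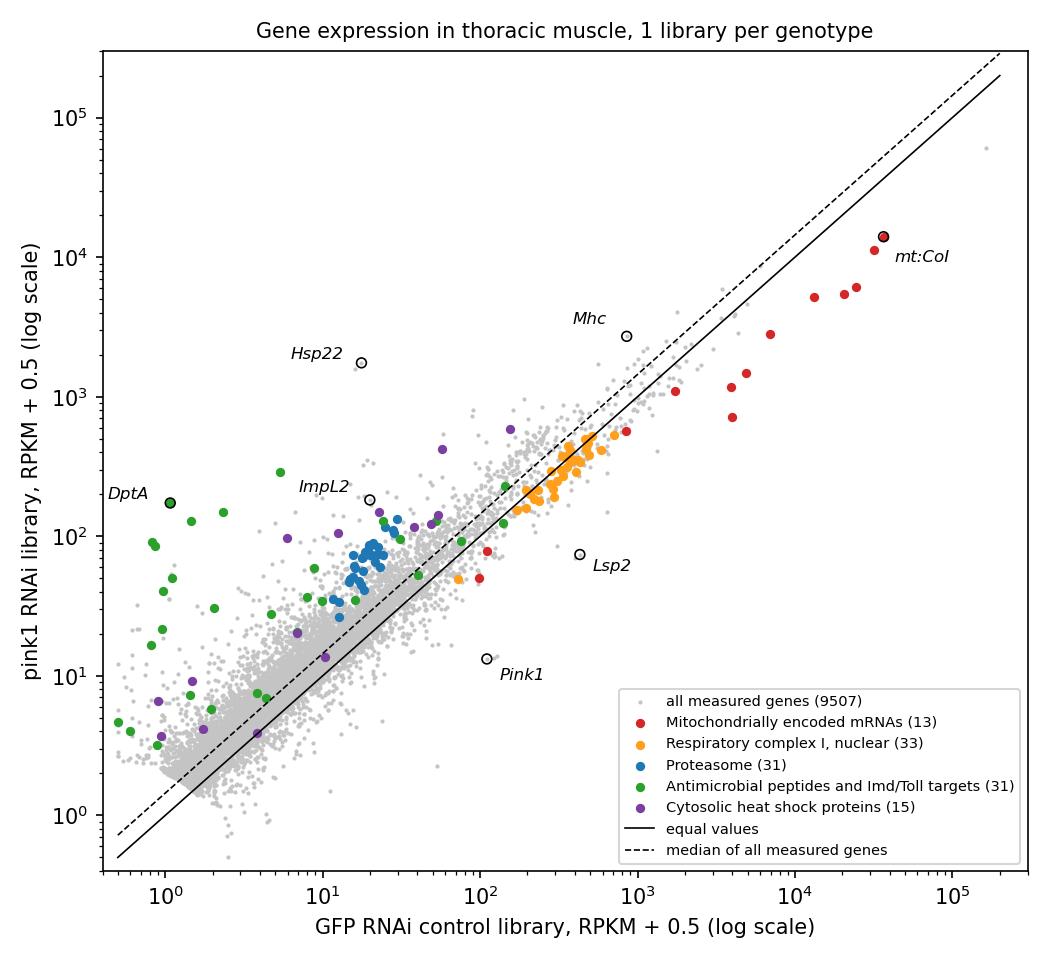
RPKM of each measured gene in the pink1 RNAi library against the GFP RNAi control, both on log axes, with 1 point per gene and selected gene groups in colour. The solid line marks equal values and the dashed line the median ratio of all genes (1.44-fold); circled genes include Pink1 (12.7 against 110.0 RPKM) and Hsp22 (1748 against 17.1 RPKM).

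Antimicrobial peptide genes, the secreted effectors of the Imd and Toll immune pathways, included 7 of the 12 genes with the highest ratios. DptA, a diptericin, lay at 173 RPKM in the pink1 RNAi library and 0.577 in the control, which was 299-fold higher (interval 145 to 746, from 2182 and 7 reads). Dro lay at 90.1 against 0.325 RPKM, AttA at 84.3 against 0.362, AttC at 127 against 0.954, DptB at 149.8 against 1.82, Mtk at 291 against 4.88 and CecA1 at 49.6 against 0.603. The group also took in other targets of the Imd and Toll pathways. Of 31 measured genes in the group, 25 were at least 2-fold higher on the deposited scale and 23 were at least 2-fold above the median of all genes, while none was 2-fold lower on either scale. The group median was 1.89 above that of all genes (interval over members 1.04 to 3.82), higher than in all 10000 random lists matched on expression. The abundant peptide gene BomS2 differed less, at 229 against 143 RPKM. AttA, AttB and the CecA genes have close copies, so the division of reads among them is uncertain. The most abundant fat body and haemocyte markers, from tissues that also make these peptides, lay below the median of all genes, as given with the tissue markers.

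Chaperones of mitochondria and of the cytosol were also higher. The small mitochondrial heat shock protein gene Hsp22 reached 1748 RPKM against 17.1, a 102-fold difference (95.1 to 109). The exons of Hsp22 lie wholly within CG4456, which had nearly the same reads, so the 2 genes cannot be separated. Among mitochondrial chaperones, proteases and prohibitins, Phb2 lay at 192 against 16.4 RPKM (11.7-fold), Hsc70-5 at 538 against 57.4 (9.38-fold) and Phb1 at 75.8 against 10.3 (7.38-fold). In this group 11 of 12 genes were at least 2-fold higher on the deposited scale, 8 of them at least 2-fold above the median of all genes, and ClpX, named after its value was seen, was lower at 59.1 against 87.7 RPKM. The group median was 2.01 (0.62 to 2.69) and lay above all matched random lists. Of 15 cytosolic heat shock genes, 13 were at least 2-fold higher on the deposited scale and 10 at least 2-fold above the median of all genes, with a group median of 1.39 (0.80 to 2.35), again above all matched random lists. Hsp23 lay at 96.2 against 5.46 RPKM, Hsp68 at 106 against 12, Hsp83 at 421 against 56.7 and Hsc70-4 at 589.5 against 155. Hsp70Bc lay at 6.11 against 0.394 RPKM, but the Hsp70 genes are nearly identical copies and their separate values are uncertain.

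All 31 measured proteasome genes were at least 2-fold higher on the deposited scale, and 25 of them were at least 2-fold above the median of all genes. The proteasome degrades proteins tagged with ubiquitin. Prosbeta4 lay at 72.6 against 15 RPKM, Prosbeta7 at 116 against 24.5 and Prosbeta5 at 132 against 29.0. The group median was 1.30 (1.13 to 1.43), above all matched random lists. The autophagy genes did not share this difference, with a median of 0.27 on the deposited scale that turned to -0.26 relative to all genes (-0.56 to -0.00; percentile 0.34). Within that group ref(2)P, the fly p62 cargo receptor, was nevertheless 4.69-fold higher at 266 against 56.6 RPKM, and Atg1 was 2.70-fold higher, whereas Atg8a lay at 374 against 388 RPKM.

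Transcripts for the respiratory chain were lower relative to other genes, whether encoded in the mitochondrion or in the nucleus. All 13 mitochondrially encoded mRNAs were lower, 9 of them at least 2-fold on the deposited scale and all 13 at least 2-fold below the median of all genes, and their median was -1.91 relative to all genes (-2.46 to -1.19), below all matched random lists. mt:ATPase8 was 5.62-fold lower, mt:ATPase6 lay at 6075 against 24463 RPKM, mt:Cyt-b at 5405 against 20615 and mt:ND5 at 1182 against 3935. The most abundant mRNA, mt:CoI, lay at 14008 against 36535 RPKM, 2.61-fold lower (2.6 to 2.62), and mt:CoIII was 2.82-fold lower. The small ribosomal RNA mt:srRNA lay at 149 against 637 RPKM.

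The nuclear genes of oxidative phosphorylation differed by less than the mitochondrial ones. Of 68 measured, all 68 lay below the median of all genes, 53 had a log2 ratio below 0 on the deposited scale, and none differed 2-fold on that scale. At least 2-fold below the median of all genes were 4 genes of complex I, 6 of complexes II to IV and 2 of ATP synthase. Their joint median was -0.73 relative to all genes (-0.83 to -0.67). For complex I it was -0.69 (-0.83 to -0.59; 33 genes, percentile 0.01), for complexes II to IV -0.77 (-1.01 to -0.63; 22 genes, percentile 0.03) and for ATP synthase -0.71 (-0.93 to -0.52; 13 genes, percentile 1.2). ND-B8 lay at 191 against 293 RPKM, ox at 744 against 1244, SdhC at 315 against 495, COX5A at 1308 against 1821 and ATPsynF at 1098 against 1691. The abundant genes ND-49, levy and blw had log2 ratios of 0.02, -0.06 and -0.08 on the deposited scale. Relative to all genes they lay at -0.51, -0.59 and -0.61.

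Mitochondrial ribosomal protein genes, which are nuclear and serve translation inside the organelle, were higher. Of 71 measured, 52 were at least 2-fold higher on the deposited scale and 25 were at least 2-fold above the median of all genes. Their median was 0.83 (0.69 to 0.98), above all matched random lists. mRpS31 lay at 21.1 against 4.03 RPKM and mRpL12 at 43.3 against 9.36. Cytosolic ribosomal protein genes had a smaller and very even difference, with 53 of 75 at least 2-fold higher on the deposited scale, 74 above the median of all genes but none by 2-fold, and a median of 0.53 (0.50 to 0.60; above all matched random lists). RpL8 lay at 475 against 185 RPKM and RpS3A at 609.7 against 241.

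The mitochondrial import genes had a median of 0.35 (0.17 to 0.96; 11 genes, percentile 95.2), inside the range of random lists, although Tom40 was 4.08-fold higher at 35.9 against 8.79 RPKM. The genes of the PINK1 and Parkin pathway had no common direction, with a median of 0.04 (percentile 59.4). In that group the protease gene Lon lay at 39.5 against 11.2 RPKM and clu at 57.9 against 18.7, whereas Marf lay at 123 against 115.3. Genes of mitochondrial DNA maintenance had a median of 0.14 (percentile 82.9), with TFAM at 44.6 against 27.4 RPKM.

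**Figure D2:**
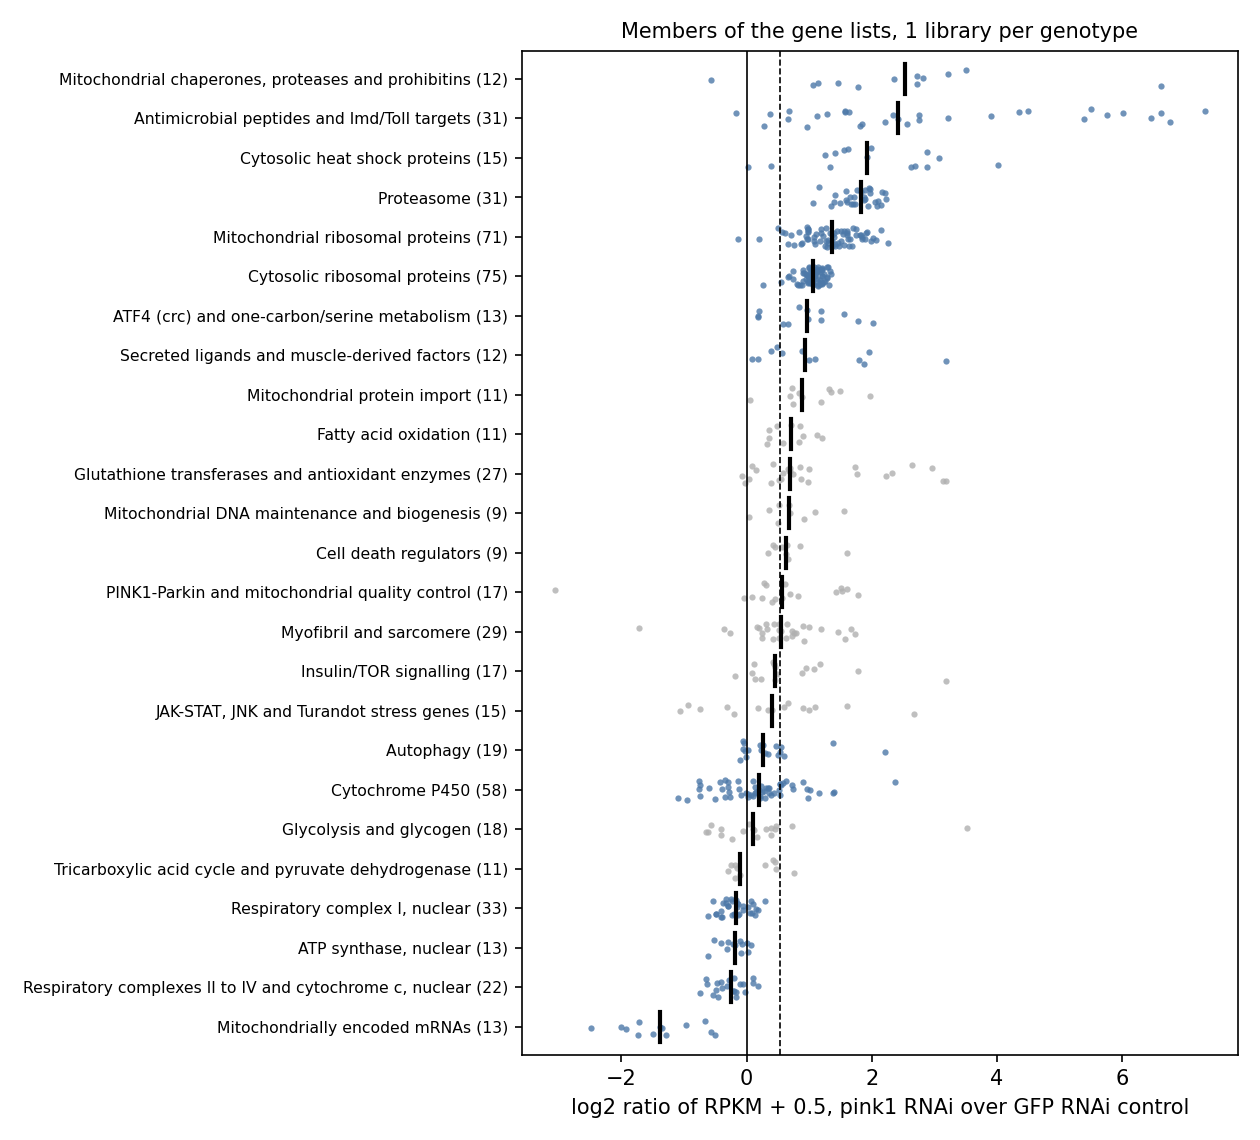
Log2 ratios of pink1 RNAi to control for the measured members of each gene group, with 1 point per gene and a black bar at each group median. The solid line marks 0 and the dashed line the median of all genes (0.53); blue groups have medians outside the central 95% of matched random lists and grey groups lie inside it.

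ImpL2, a secreted protein that binds and antagonises insulin-like peptides, was 9.34-fold higher in the pink1 RNAi library (8.81 to 9.90), at 182 against 19.4 RPKM from 12335 and 1269 reads. ImpL2 spans 4224006 to 4236147 on chromosome 3L. Thor, the fly 4E-BP that restrains translation, lay at 688 against 200.5 RPKM (3.43-fold), and the growth regulators Sesn and gig lay at 73.7 against 32.4 and 8.55 against 3.78. As a group the 17 insulin and TOR genes had no common direction, with a median of 0.45 on the deposited scale that turned to -0.08 relative to all genes (percentile 21.3). Among 12 secreted ligand genes, 5 were at least 2-fold higher on the deposited scale, 4 were at least 2-fold above the median of all genes and none was 2-fold lower, and their median was 0.41 (-0.14 to 1.35; percentile 99.4). The FGF gene bnl lay at 11.4 against 2.57 RPKM, the activin-like gene daw at 21.0 against 5.37 and Fs, the fly follistatin, at 5.16 against 1.12, whereas myo lay at 24.6 against 21.5. ImpL2 and Thor each belong to 2 of these groups, so the groups are not independent. The group of ATF4 (crc) and serine and folate metabolism had a median of 0.44 (-0.33 to 1.03; 13 genes, percentile 98.4), with crc at 207 against 116 RPKM, eIF2alpha at 57.9 against 13.8, PEK at 14.4 against 4.58 and Nmdmc at 22.5 against 9.52. Of the 13, 10 lay above the median of all genes and 3 below it. The 3 were Shmt at -0.33, CG6287 at -0.34 and pug at -0.35 relative to all genes, named after their values were seen.

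Central metabolism was marked by a difference in Ldh, the enzyme that converts pyruvate to lactate. It lay at 38.1 against 2.84 RPKM, 13.4-fold higher (11.2 to 16.1). The other glycolytic genes did not follow, since 16 of the 18 genes in the group lay below the median of all genes, Gapdh1 at 2854 against 4364 RPKM and Pgk at 272 against 425. The glycolysis median was 0.11 on the deposited scale and -0.42 relative to all genes (-0.93 to -0.14; percentile 6.12). The tricarboxylic acid cycle genes had a median of -0.63 (-0.77 to -0.06; 11 genes, percentile 3.18), with mAcon1 at 1798 against 2047 RPKM, while Scsalpha1 lay at 581 against 343. Fatty acid oxidation genes had a median of 0.18 (11 genes, percentile 77.3). On the deposited scale CPT2 was 2.38-fold and Mtpalpha 2.21-fold higher, but none of the 11 was at least 2-fold above the median of all genes.

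Genes of detoxification and stress signalling were mixed. Some glutathione transferase genes were higher, among them GstD1 at 808 against 160.5 RPKM, GstD9 at 47.3 against 4.73 and GstD3 at 34.5 against 3.45 and GstS1 at 847 against 248. In the whole group of 27 glutathione transferase and antioxidant genes 8 were at least 2-fold higher on the deposited scale and 8 at least 2-fold above the median of all genes, and the median was 0.17 (-0.01 to 1.21; percentile 93.2, inside the range of random lists). The cytochrome P450 genes had a median of 0.21 on the deposited scale that turned to -0.32 relative to all genes (-0.51 to -0.18; 58 genes, below all matched random lists). The list was drawn up by symbol prefix and also took in Cyp40, a cyclophilin, without which the median of 57 genes was -0.33. Cyp6a8 was 8.09-fold higher at 5.76 against 0.711 RPKM, and Cyp4g1, which makes cuticular hydrocarbons in oenocytes, was 1.94-fold lower at 247 against 479. Gadd45 lay at 55.1 against 8.18 RPKM and egr, the fly TNF, at 11.7 against 5.21, while TotA lay at 72.1 against 138 and TotX at 5.74 against 12.6. That group of JAK-STAT, JNK and Turandot genes had a median of 0.40 on the deposited scale and -0.13 relative to all genes (15 genes, percentile 10.9). Cell death regulators had a median of 0.11 (9 genes, percentile 77.8), with the cell death gene rpr at 2.40 against 0.454 RPKM.

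The sarcomere genes as a group lay at the median of all genes, at 0.02 (-0.21 to 0.26; 29 genes, percentile 68.4). Single members differed in both directions. The myosin heavy chain gene Mhc lay at 2709 against 853 RPKM (3.17-fold higher), Msp300 at 80.8 against 23.9 and the flight muscle actin gene Act88F at 4047 against 1771, whereas Mf, myofilin, was 3.29-fold lower at 405 against 1335.

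Several of the lowest genes lay outside the gene groups described so far. CG18628 lay at 1.76 against 53.0 RPKM, 30.05-fold lower (18 to 54.2, from 15 and 433 reads), the odorant-binding protein gene Obp99b at 13.3 against 127 and CG6664 at 16.2 against 64.9. The larval serum protein genes Lsp1beta and Lsp2 lay at 12.9 against 123 RPKM and 73.6 against 430.0. Lsp2 overlaps the antisense gene asRNA:CR11538 by 84.6%, so reads of these genes cannot be separated. MFS3, CG7130 and lncRNA:CR44138 were among the 12 highest, at 62.2 against 0.645, 53.3 against 0.583 and 31.9 against 0.166 RPKM; the control value of lncRNA:CR44138 rested on 2 reads, and its ratio of 192 had an interval of 52.8 to 1592.

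Markers of other tissues, among them reproductive organs outside the thorax, were measured beside these groups. Fat body markers had a median of -0.78 (-3.07 to 0.41; 8 genes, percentile 0.02), and their most abundant members Desat1 and apolpp lay at 591 against 461 and 299 against 326 RPKM. Of the 8, 7 lay below the median of all genes and 1 above it, bmm, at 27.1 against 13.9 RPKM. Haemocyte markers had a median of 0.28 on the deposited scale and -0.25 relative to all genes (9 genes, percentile 4.67), with Col4a1 at 58 against 47.0 RPKM and PPO2 at 5.93 against 12.4. Of the 9, 7 lay below the median of all genes and 2 above it, among them crq at 35.7 against 19.0 RPKM. Gut markers had a median of -0.57 (-0.90 to 0.20; 27 genes, below all matched random lists), with alphaTry at 127 against 141 RPKM. The list of cuticle and epidermis markers, drawn up by symbol prefix, held 28 measured genes including Cpr, a P450 reductase that is no cuticle protein. Its median was 0.33 (-0.19 to 0.51; percentile 99.9), and 0.35 (-0.24 to 0.53; percentile 99.8) for the 27 genes without Cpr, with Cpr47Ef at 85.3 against 13.7 RPKM and Cpr100A at 55.5 against 17.7, and the median of the whole list turned to -0.24 without the filter on low values. Neuron markers had a median of 0.36 on the deposited scale and -0.17 relative to all genes (14 genes, percentile 7.5), and glia markers 0.27 and -0.26 (7 genes, percentile 9.39). Testis and accessory gland markers had a median of 0.10 on the deposited scale that turned to -0.43 relative to all genes (10 genes, percentile 0.14), all with values of a few RPKM. Of the female markers 3 were measured, the yolk protein genes Yp1, Yp2 and Yp3, at 3.05 against 3.81, 1.99 against 2.83 and 2.40 against 3.04 RPKM, where the value of Yp1 is uncertain because an antisense gene overlaps 54.3% of its exons.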

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

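The scaling without mitochondrially encoded genes, the size rule on recovered reads, the restriction to protein-coding genes and the lists without Cyp40 and Cpr were chosen after seeing the data. Counts of genes depended on the scale and on thresholds. Higher genes numbered 491 with the median ratio set to 1, 768 without the 20 most abundant genes in the total, 714 without the mitochondrially encoded genes, 1022 with a pseudocount of 2 and 821 with a minimum of 10 RPKM. Lower genes numbered 285, 251, 243, 51 and 42 under the same settings, and 133 with no filter. The 3 scalings by construction moved the all-gene median from 0.53, to -0.00, 0.14 and 0.12. A larger pseudocount by construction shrinks ratios of low genes, and the filters changed the genes compared from 9507 to 3625 (minimum of 10) or 15368 (none). All 82 lower genes were shared under each of the 3 scalings. Each scaling lowers the pink1 RNAi values against the control by a common factor. A gene already lower can thus only become lower, and this sharing is no check of stability. Pseudocount 0.1, thinning, recovered reads and protein-coding genes gave 1961, 1627, 1540 and 1461 higher and 98, 82, 72 and 70 lower genes. The Pink1 log2 ratio was -3.63, -3.51 and -3.53 under the scalings and -2.93 with a pseudocount of 2. By construction none of these settings could turn the Pink1 ratio positive. Among groups outside the range of random lists, 3 medians that were positive on the deposited scale turned negative when rescaled. Cytochrome P450 genes gave -0.34, -0.20 and -0.22 (median ratio, 20 most abundant, mitochondrial), autophagy genes -0.24, -0.10 and -0.12, and testis and accessory gland markers -0.55, -0.45 and -0.28. Among groups inside that range, the glycolysis, JAK-STAT, neuron, glia and haemocyte medians turned negative under all 3 scalings, from -0.48 to -0.02, insulin and TOR genes gave -0.13, 0.02 and -0.00, and the PINK1 and Parkin genes -0.02 with the median ratio set to 1. With no filter the gut median on the deposited scale turned to 0.11 and the cuticle median relative to all genes to -0.24; the cause was not tested. Under the settings run for groups, 6 to 10 groups lay above and 7 to 11 below the range of random lists, against 9 and 9 as reported. Over all pairs of a result and an alternative, 978 stayed within their interval or, for counts, within 1.5 times, 687 moved and 11 for groups outside the range reversed. Of the moved, 178, 168 and 173 were named genes under the 3 scalings, which shift all genes together by construction. Thinning removed few reads, since the libraries had similar depth. The totals are therefore no measure of stability. Scaling to a plain total was not run, since RPKM already divides by it, and leaving out a library would empty a genotype. No paired analysis was possible because the labels give no replicate numbers and each genotype had 1 library. Depth limits genes with few reads, such as DptA with 7 reads in the control.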

Other observations

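The 5 gene groups described here, and all tests weighed here except that of gene length, were chosen after the results were seen. The positions of these 5 groups among random lists come from the same values that led to their choice. They describe the groups and are no independent support. Genes that charge tRNAs with amino acids were higher in the pink1 RNAi library, both for cytosolic and for mitochondrial translation. Of 17 cytosolic aminoacyl-tRNA synthetase genes 16 were at least 2-fold higher on the deposited scale and 7 at least 2-fold above the median of all genes. Their median was 0.96 relative to all genes (interval over members 0.74 to 1.40), above all matched random lists. GluProRS lay at 186 against 9.34 RPKM, TrpRS at 34.6 against 3.13 and IleRS at 29.9 against 5.25. Of 13 mitochondrial synthetase genes 11 were at least 2-fold higher on the deposited scale and 4 at least 2-fold above the median of all genes, with a median of 0.88 (0.51 to 1.03), also above all matched random lists, and ValRS-m lay at 4.36 against 0.779 RPKM. The translation initiation factors eIF2, eIF2B and eIF3 had 20 of 21 genes at least 2-fold higher on the deposited scale, 8 at least 2-fold above the median of all genes, and a median of 0.91 (0.63 to 1.16), above all matched random lists. Among them eIF2beta lay at 129.6 RPKM in the pink1 RNAi library, a log2 ratio of 2.93, and eIF2Bgamma at 24.1 against 4.81 RPKM.

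Genes of the CCT chaperonin and of endoplasmic reticulum folding were higher too. All 7 measured subunits of CCT, the cytosolic chaperonin that folds actin and tubulin, were at least 2-fold higher on the deposited scale and 3 were at least 2-fold above the median of all genes, with a median of 0.96 (0.68 to 2.16; percentile 99.9) and CCT5 at 35.5 against 5.10 RPKM. Of 15 genes for endoplasmic reticulum chaperones and the unfolded protein response, 9 were at least 2-fold higher on the deposited scale and 7 at least 2-fold above the median of all genes, and the median was 0.82 (0.23 to 1.48), above the central 95% of matched random lists. Hsc70-3, the fly BiP and a member of the Hsp70 family, lay at 245 against 47.4 RPKM, CaBP1 at 37.1 against 7.28, Manf at 43.6 against 9.07 and Xbp1 at 221 against 66.9. PEK and eIF2alpha are also in the ATF4 group, so these groups share members with it.

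Mitochondrially encoded transcripts were lower in the pink1 RNAi library. Less muscle in the dissected thoraces would lower sarcomere genes as well, which was argued against by their median of 0.019 relative to all genes. A loss of mitochondrial RNA during preparation stays open. On the deposited scale the 5 mitochondrial mRNAs with the most reads ran from -2.01 to -1.35, a span of 0.66 in log2. All 13 ran from -2.49 to -0.50. Without replicate libraries the spread between preparations is unknown. An effect of the knockdown on mitochondrial RNA also stays open as a hypothesis, and the nuclear oxidative phosphorylation genes, at -0.73, went in the same direction. These cannot be told apart, since each genotype had 1 library.

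Heat shock, mitochondrial chaperone and proteasome genes were higher together. A trend with gene length was argued against, since the proteasome median lay at percentile 100 among 10000 lists matched on exon length and expression, whose highest median was 0.64 relative to all genes. The change of scale from the mitochondrial reads was argued against as the whole cause, since the proteasome median was still 1.38 (1.21 to 1.52) with those reads left out of the total. A heat exposure of the flies of this library was weighed by whether the Hsp70 copies together exceed Hsp22. In the pink1 RNAi library the 6 copies summed to 32.1 RPKM (11.8 in the control), far below Hsp22 at 1748 RPKM. Reads shared by such near-identical copies may have been dropped, which leaves this test undecided, and heat may still have contributed. An effect of pink1 silencing stays open and cannot be told apart from such an exposure with 1 library per genotype.

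Antimicrobial peptide genes were higher in the pink1 RNAi library. More fat body or haemocyte tissue would bring the abundant transcripts of those tissues, but the highest of Desat1, apolpp, Col4a1 and vkg was Desat1, at -0.17 relative to all genes. The group of antimicrobial peptides and other Imd and Toll targets had a median of 1.89 relative to all genes. A microbial exposure of the flies of this library may account for it, and so may an effect of silencing pink1 in muscle. These cannot be told apart here, since each genotype had 1 library. For this pattern and those above, any other difference between the genotypes also goes with the knockdown.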
